A study of Mus musculus with 8 samples.

How the data were processed

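Whole ear skin of adult wild-type C57Bl/6 mice was profiled by RNA sequencing in 8 libraries, 4 from mice given the ethanol vehicle and 4 from mice given MC903. MC903 is calcipotriol, a vitamin D analog, applied to the skin at 1 nmol daily for 12 days. Per the labels' protocols, total RNA was treated with DNase, and 1 ug went into each library. Ribosomal RNA was removed by hybridization, cDNA was primed with random hexamers, and the ligated fragments were amplified over 12 cycles with indexed primers. Single reads of 50 bases were sequenced on an Illumina HiSeq-3000. The protocol has no step that marks strand, and no strand setting was stated, so reads of a gene and of an overlapping antisense gene were not told apart.

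The authors deposited 1 table per library with whole-number counts of reads per Ensembl gene, and beside them CPM and RPKM. Per the submitters' processing notes, the tools were STAR 2.0.4b, Subread and featureCounts 1.4.5, on the genome build mm10. The annotation release and the handling of multiply mapped reads were not given in the sources used here. The deposited CPM values equalled each count scaled by the library's total to within 2.04e-10, and the deposited RPKM values equalled that CPM per kilobase of gene length to within 5.82e-11. Both were used only for this check, and every result rests on the deposited counts.

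The tables held 41388 gene identifiers. Of these, 40254 were named from a table of gene symbols, 151 by position (same strand and at least 90% overlap in both directions with a GENCODE M21 gene), and 983 stayed unnamed. Flg was among those named by position. Trdc and Krt85, members of the lists described below, were not matched and were not analysed here. Interleukin 36 alpha, beta and gamma carry the symbols Il1f6, Il1f8 and Il1f9.

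Library totals ran from 12310466 to 16837221 counts. A count of 3 corresponded to 0.178 to 0.244 CPM, which was taken as the detection floor. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Libraries within a group differed by far more than sampling noise in a chi-square comparison (chi-square per degree of freedom 11.1 at the lowest), so none was treated as a repeat of another.

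Genes were filtered with filterByExpr by group, normalized with TMM factors and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, group as the only term). Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM values given in the results are TMM-adjusted. The count of changes of at least 2-fold used the estimated fold change, with a glmTreat test against that minimum as an alternative.

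A set of 37 gene lists was fixed before the data were examined. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and beside it with an estimated correlation and with fry. The mean log2 CPM of each list was also compared between groups with a two-sided exact permutation test, whose smallest possible p for 4 against 4 libraries is 0.0286. Counts of called members are over all genes tested, and are also given adjusted over the list alone.

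Genes were named by a rule fixed at the same point. It takes Cyp24a1 as the treatment check and 12 other preset genes. It adds the 6 largest rises and 6 largest falls among called genes whose 4 values in one group all lay beyond the 4 of the other, at an average log2 CPM of at least 1 and without predicted or clone names. It further takes the 2 members with the smallest p from each list of biological processes, 1 from each marker or technical list, and every type 2 cytokine. Some genes the rule names are not reported here. Other genes named in the text, including further list members, were chosen after their values were seen.

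The same fit was tested on simulated data for the comparison of MC903 with vehicle, over 15640 genes with the real vehicle means, library sizes and dispersions. It called 13 of 49 genes changed by 1.5-fold, 38 of 50 changed by 2-fold, 49 of 49 changed by 4-fold and 48 of 48 changed by 8-fold. Of all its calls, 8.64% were unchanged genes. Only the genes counted here were changed in the simulation, whereas 41.5% of the genes tested were called in the real data. These rates may therefore not hold for the real comparison.

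Alternatives covered other normalizations, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, robust dispersion, the replicate number as a block, thinning to the shallowest library, leaving out mitochondrial and ribosomal RNA genes, and leaving out each library in turn. DESeq2 list tests used cameraPR on signed normal scores of its p-values. Subtraction of reads that may have crossed between libraries was added after seeing the data. The ratio intervals used Python 3.11.15 with scipy 1.17.1.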

Results

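Ear skin of 4 vehicle-treated and 4 MC903-treated mice was compared to find which genes differ after 12 days of the vitamin D analog, a treatment used to produce itchy, atopic dermatitis-like skin inflammation in mice. Library totals were 14223908 to 16837221 counts in the vehicle group and 12310466 to 15575518 in the MC903 group, with 22205 to 23092 genes detected per library. All samples were whole ear tissue, so a change in a gene's level can reflect its regulation or a change in the cells that make up the ear.

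Many genes differed between MC903-treated and vehicle-treated ears. Cyp24a1, the vitamin D-degrading enzyme and a direct target of the vitamin D receptor, rose from 18.8 ± 1.73 to 3837 ± 403 CPM (mean ± SD, n = 4 per group), a log2 fold change of 7.67 ± 0.23 (SE; adjusted p = 1.76e-08). The gene, ENSMUSG00000038567, lies on chromosome 2 from 170482708 to 170497145 in mm10. Of 16105 genes tested, 6682 passed the threshold, 3423 of them higher and 3259 lower in MC903 skin. The share higher, 51.2%, depended on normalization and was 44.0% with library sizes alone and 43.1% with upper quartile factors. Changes of at least 2-fold numbered 2747, with 1513 higher and 1234 lower. Tested against a 2-fold minimum with glmTreat, 1051 genes passed, 774 higher and 277 lower. The first principal component held 68.5% of the variance and separated the groups.

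The 6 largest rises by the fixed rule were Chil4 (a chitinase-like protein, log2 fold change 8.04 ± 0.51), H1foo (an oocyte linker histone, 8.02 ± 0.68), Cyp24a1, Akr1d1 (a steroid reductase, 7.50 ± 0.29), Sprr2k (7.45 ± 0.56) and Lce3b (7.41 ± 0.41). H1foo and Sprr2k had 1 and 2 counts over the 4 vehicle libraries, all in vehicle replicate 4, so their fitted fold changes depend on the prior count and their ratios are wide, 389 (95% exact interval 69.4 to 15420) and 214 (58.8 to 1771). The summed vehicle counts of Chil4, Cyp24a1, Akr1d1 and Lce3b were only 0.465%, 0.569%, 0.646% and 0.649% of the MC903 counts. Salivary transcripts abundant in vehicle replicate 2 stood in the other libraries at a pooled share of their count there with a median over libraries of 0.0556%. Summed over the 4 vehicle libraries, that rate would give 0.222% of the MC903 counts. This equals 47.8%, 39.05%, 34.4% and 34.2% of the vehicle counts of Chil4, Cyp24a1, Akr1d1 and Lce3b. With reads subtracted at that rate from every library, an alternative chosen after seeing the data, the log2 fold changes were 8.96, 8.39, 8.07 and 7.78. The transcripts behind the rate were chosen after their values were seen, and Amy1, Car6 and Dnase1, which stood higher (up to 0.477%), were left out. The rate depends on that choice, and whether it is too low or too high for crossed reads was not tested. The 6 largest falls were all hair keratin-associated proteins: Krtap15 (-4.25 ± 0.84), Krtap26-1 (-4.20 ± 0.97), Krtap6-1 (-4.14 ± 0.91), Krtap4-2 (-4.13 ± 0.95), Krtap4-7 (-4.03 ± 0.95) and Krtap19-3 (-3.97 ± 0.96). Their vehicle levels were uneven, as in Krtap15 at 31.3 ± 37.7 CPM against 1.596 ± 1.29 CPM in MC903 skin, and depended on vehicle replicate 4. Without that library the 6 log2 fold changes, still called, were -2.95, -2.76, -2.92, -2.62, -2.42 and -2.31. Sprr2, Lce3, Chil3 and Chil4, Krtap, Krt6, Serpinb3 and beta-defensin genes have close relatives, and how reads shared between them were counted was not stated, so the levels of single members are uncertain.

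**Figure D1:**
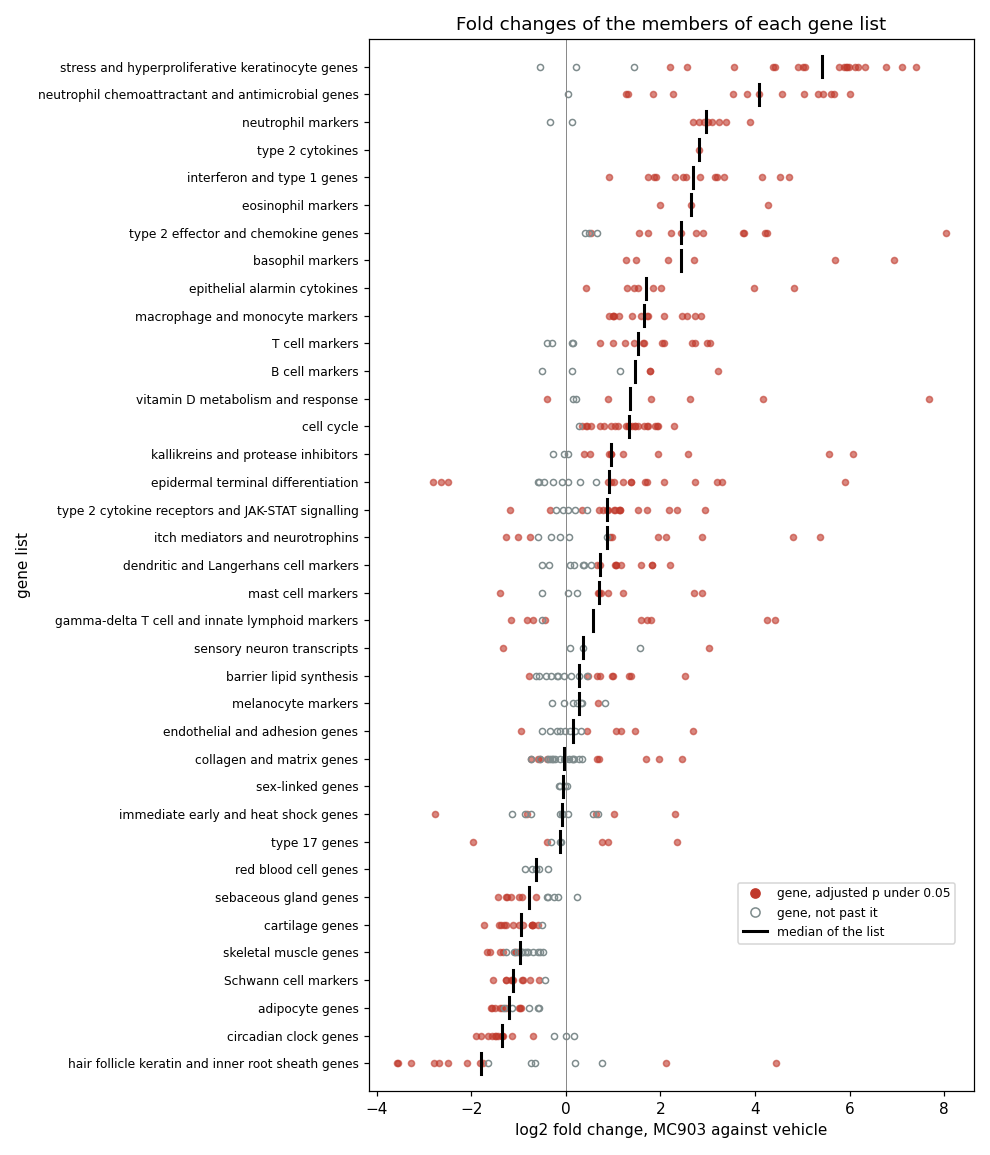
Log2 fold change (horizontal axis, MC903 against vehicle) of every measured member of each gene list (vertical axis). Filled points passed the adjusted threshold, open points did not, and black bars mark the list medians, which run from -1.79 for the hair follicle list to 5.42 for the stress keratinocyte list.

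All 8 measured members of the epithelial alarmin list, 6 of them interleukin 1, 18 or 36 genes, were higher (median log2 fold change 1.69, camera adjusted p = 2.42e-09). Tslp rose from 16.8 ± 3.57 to 479 ± 208 CPM (4.83 ± 0.33, adjusted p = 1.99e-06), Il33 from 103 ± 30.8 to 255 ± 34.9 CPM (1.30 ± 0.21), and Il1a by 2.005 ± 0.14. In the vitamin D list, 5 of 8 measured members were higher and 1 lower (median 1.35, adjusted p = 1.69e-05), with Cd14 at 2.62 ± 0.35. The receptor Vdr itself was 74.6 ± 11.5 CPM in vehicle and 86.9 ± 8.89 CPM in MC903 skin and did not pass the test (adjusted p = 0.219), and its partner Rxra was lower (-0.41 ± 0.11).

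Il4 was the only type 2 cytokine of the 6 listed with enough counts to test, and it rose from 1.26 ± 0.18 to 8.94 ± 2.56 CPM (2.82 ± 0.24, adjusted p = 7.34e-06; list camera adjusted p = 0.0105, a list of 1 measured gene, not called with limma-voom, adjusted p = 0.0670). The other members were near the floor; 1 more member passed the filter and was called higher in the fits without any 1 vehicle replicate or without MC903 replicate 4. Il13 had 8 counts over the 4 vehicle libraries and 43 over the 4 MC903 libraries, a ratio of 6.00 with a 95% exact interval of 2.79 to 14.8. Il3 had 0 and 17 counts, a ratio of 6.32 if 3 counts are set for the vehicle group as a whole. That ratio leaves out the counting error of the 17 and is not a lower limit. Il5 had 7 and 9 counts, Il9 had 2 and 0, and Il31 had 0 and 3, so differences in these genes were not detectable at this depth.

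Of the type 2 effector and chemokine list, 12 of 15 measured genes were higher and none lower (median 2.44, adjusted p = 3.66e-16), or 13 adjusted over the list alone. Chil4 and Chil3 (3.74 ± 0.26) had the smallest p, and Arg1 (4.26 ± 0.32) and Ccl17 (2.75 ± 0.24) also rose. Cytokine receptors and JAK-STAT genes rose in 15 of 22 cases and fell in 2 (median 0.88, adjusted p = 1.95e-05). Il4ra rose from 17.3 ± 2.70 to 88.3 ± 7.24 CPM (2.35 ± 0.14, adjusted p = 6.61e-07), Csf2rb by 2.19 ± 0.17, Il13ra1 by 0.87 ± 0.16 and Osmr by 0.88 ± 0.14. Il31ra, a subunit of the interleukin 31 receptor, was higher by 1.02 ± 0.34 (adjusted p = 0.0312). Its call was lost without vehicle replicate 1 (adjusted p = 0.0549), 2 (0.0702) or 3 (0.0527) and without MC903 replicate 4 (0.0799), and its adjusted p ran from 0.00764 to 0.0799 over all alternatives. The kinase Jak1 was 262 ± 35.5 CPM in vehicle and 300 ± 34.3 CPM in MC903 skin and did not pass the test (0.19 ± 0.15, adjusted p = 0.324), while Stat5b and Il17rb were lower (-0.34 ± 0.11 and -1.18 ± 0.17); 1 member of the list was lower without vehicle replicate 1 or 4 or MC903 replicate 3.

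Itch mediators and neurotrophins went both ways, with 7 of 15 measured members higher and 3 lower (median 0.86, camera adjusted p = 0.00611; not called with limma-voom, adjusted p = 0.0986), or 8 higher and 3 lower adjusted over the list alone. Hdc, which makes histamine, rose by 2.88 ± 0.18 and Osm, oncostatin M, by 4.81 ± 0.35. Edn1, endothelin 1, and Bdnf fell by 1.27 and 1.02 on the log2 scale. Only 5 of 16 sensory neuron transcripts passed the filter. Of these, 1 was higher and 1 lower, the latter being the neuropeptide gene Calcb (-1.33 ± 0.23), and the list was not called (adjusted p = 0.647; 2 higher and 1 lower adjusted over the list alone). Without vehicle replicate 2 or MC903 replicate 1 or 4, 2 of its members were higher.

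All 14 measured interferon and type 1 genes were higher (median 2.69), including the chemokines Cxcl9 (4.53 ± 0.20) and Cxcl10 (4.72 ± 0.35). The list's camera adjusted p was 1.77e-16, and 0.0442 with an estimated correlation. Ifng itself had 0 counts in vehicle and 65 in MC903 skin, a ratio of 24.2 if 3 counts are set for the vehicle group as a whole. That ratio leaves out the counting error of the 65 and is not a lower limit. Of the type 17 genes, 3 of 8 were higher and 2 lower (adjusted p = 0.988), and the median (-0.12) and mean (0.13) of the list differed in sign. Il17rc rose by 0.89 ± 0.13. Only 1 type 17 gene was lower without vehicle replicate 1, 2 or 4 or MC903 replicate 1, 3 or 4. Neutrophil chemoattractants and antimicrobial genes were higher in 14 of 15 cases (median 4.09, adjusted p = 6.24e-16, or 0.0403 with an estimated correlation). Defb14 rose by 4.09 ± 0.22 and Reg3g by 6.00 ± 0.40, though Reg3g lay below the floor in vehicle skin (0.129 ± 0.0977 CPM).

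Stress and hyperproliferative keratinocyte genes, measured in whole ear, showed the highest list median, 5.42. Of 22 measured, 19 were higher and none lower over all genes, and 1 was lower adjusted over the list alone. Their camera adjusted p was 2.30e-46, and 0.00866 with an estimated correlation. The gap-junction gene Gjb6 rose from 7.10 ± 1.90 to 388 ± 28.7 CPM (5.78 ± 0.21) and the protease Klk6 by 4.90 ± 0.24, and Krt16 and Krt6b rose by 5.95 ± 0.41 and 5.89 ± 0.46. The terminal differentiation list was split, with 13 of 24 members higher and 3 lower (median 0.92, adjusted p = 0.000777), or 14 and 3 adjusted over the list alone. Filaggrin, Flg, rose from 372 ± 106 to 2458 ± 631 CPM (2.72 ± 0.27, adjusted p = 1.89e-05), with Rptn (5.90 ± 0.33) and Casp14 (3.30 ± 0.20), whereas Flg2 (-2.64 ± 0.17), Lce1m (-2.81 ± 0.20) and Krt77 (-2.50 ± 0.34) fell. Members of the list of kallikreins and protease inhibitors were higher in 10 of 13 cases (median 0.94, camera adjusted p = 4.33e-06, or 0.0888 with an estimated correlation), led by Klk13 (6.08 ± 0.28) and Spink12 (5.56 ± 0.49). Barrier lipid genes had 8 of 19 members higher, among them Sult2b1 (1.33 ± 0.12) and Sptlc2 (1.00 ± 0.11), and 1 lower (2 adjusted over the list alone), and the list was not called (adjusted p = 0.0558). It was called without MC903 replicate 1 (adjusted p = 0.0325), 2 (0.0234) or 3 (0.0393), but not with an estimated correlation (adjusted p = 0.396). Its members lower numbered 2 without vehicle replicate 3, 4 without MC903 replicate 1 and 3 without MC903 replicate 4. Cell cycle genes rose in 24 of 25 cases (median 1.33, adjusted p = 6.41e-15, or 0.0378 with an estimated correlation), with Plk1 at 2.29 ± 0.18 and Cdk1 at 1.92 ± 0.16.

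**Figure D2:**
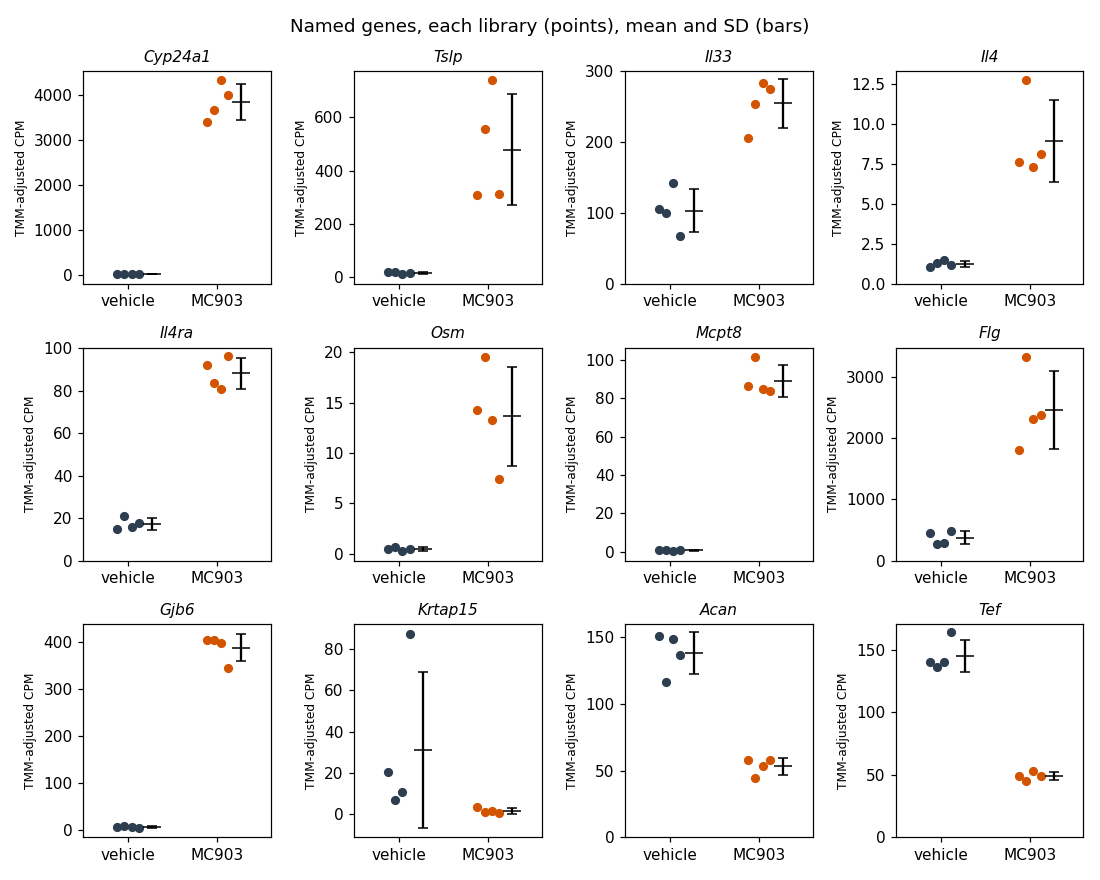
TMM-adjusted CPM (vertical axes, linear) of 12 named genes in the vehicle and MC903 groups (horizontal axes). Points are the 4 libraries of a group and bars the mean ± SD; in all 12 panels every MC903 library lies on one side of every vehicle library.

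Markers of several leukocyte types were higher. Basophil markers rose in 6 of 6 cases (median 2.43, adjusted p = 8.34e-14), led by Mcpt8, a basophil protease, from 0.722 ± 0.254 to 89.1 ± 8.33 CPM (6.95 ± 0.22). Macrophage and monocyte markers rose in 14 of 14 (median 1.65, adjusted p = 5.17e-12; C1qa 2.57 ± 0.17), neutrophil markers in 8 of 10 (median 2.97, adjusted p = 9.24e-09; Cxcr2 2.82 ± 0.15) and eosinophil markers in the 3 of 9 that passed the filter (median 2.66, adjusted p = 0.000777; Ear2 1.98 ± 0.20). Of these 3, Prg2 lay below the floor in vehicle skin (0.0455 CPM). T cell markers rose in 12 of 16 (median 1.53, camera adjusted p = 7.02e-08, or 0.0506 with an estimated correlation), with Icos at 2.98 ± 0.21. The T cell marker Cd3d rose by 1.26 ± 0.18. The 4 not called were Cd3e (-0.30 ± 0.14), Cd3g (0.12 ± 0.17), Cd247 (-0.41 ± 0.22) and Cd28 (0.15 ± 0.22), so the rise was not shared by all T cell markers. Mast cell markers rose in 7 of 11 and fell in 1 (median 0.70, adjusted p = 0.00722; adjusted p = 0.221 with an estimated correlation), with the smallest p in Hdc, which basophils also express. Dendritic and Langerhans cell markers rose in 10 of 17 (median 0.72, adjusted p = 0.000527; adjusted p = 0.161 with an estimated correlation), with Clec10a at 1.83 ± 0.15, and 1 was lower adjusted over the list alone. Gamma-delta T cell and innate lymphoid markers were split, 5 of 10 higher and 4 lower (5 lower adjusted over the list alone; median 0.57, adjusted p = 0.0448; adjusted p = 0.253 with an estimated correlation). The call was lost with DESeq2 (adjusted p = 0.0536), limma-voom (0.392), crosstalk subtracted (0.0505) and the stricter filter (0.0706), where 4 were higher and 4 lower and the median turned to -0.44. The median also depended on single libraries, being 0.31 without MC903 replicate 2, 1.66 without MC903 replicate 3, and 1.404, 1.71, 1.57 and 1.53 without vehicle replicates 1 to 4 in turn. Areg (4.42 ± 0.30) and Arg1, which other cells also express, were among those higher, and the T cell receptor genes Trdv4 (-0.82 ± 0.19) and Tcrg-V5 (-1.15 ± 0.31) among those lower. Of 6 measured B cell markers 3 were higher, or 4 adjusted over the list alone (adjusted p = 0.09004). Cd22 rose by 3.21 ± 0.47 from a vehicle level at the floor (0.183 ± 0.116 CPM). The B cell list was called without MC903 replicate 3 (adjusted p = 0.0476).

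Markers of several resident ear tissues were lower. Schwann cell genes fell in 10 of 11 cases (median -1.11, adjusted p = 1.32e-05). Cartilage genes fell in 13 of 14 cases (median -0.95, adjusted p = 1.34e-05), with aggrecan, Acan, going from 138 ± 15.8 to 53.3 ± 6.36 CPM (-1.37 ± 0.14). Adipocyte genes fell in 9 of 14 cases, or 14 adjusted over the list alone (median -1.20, adjusted p = 0.00155; adjusted p = 0.501 with an estimated correlation), with Plin4 at -1.39 ± 0.23. Only 5 adipocyte genes passed without vehicle replicate 2 or without MC903 replicate 2, and 4 without MC903 replicate 3. Sebaceous gland genes fell in 7 of 12 cases (median -0.78, adjusted p = 0.0185; adjusted p = 0.536 with an estimated correlation), with Scd3 at -1.44 ± 0.28. Skeletal muscle genes varied widely between libraries, and 6 of 18 were lower, or 4 adjusted over the list alone (median -0.98, adjusted p = 0.00848; adjusted p = 0.634 with an estimated correlation). That count ran from 0 without vehicle replicate 2 or without MC903 replicate 1 or 3 to 16 without vehicle replicate 4. It was 14 without MC903 replicate 4 and 1 without vehicle replicate 1 or 3 or MC903 replicate 2. Pvalb (-1.39 ± 0.42, adjusted p = 0.0214) was not called without vehicle replicate 1 (adjusted p = 0.0546) or 2 (0.0548) or MC903 replicate 1 (0.0503) or 3 (0.0578), with a range of 0.00191 to 0.0578 over all alternatives.

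Other resident lists were not called. Hair follicle genes had 9 of 16 members lower and 2 higher, or 11 and 2 adjusted over the list alone (median -1.79, adjusted p = 0.173). The list was called without vehicle replicate 1 (adjusted p = 0.0448) or 3 (0.0354). Tchh (4.44 ± 0.54) and Hoxc13 (2.11 ± 0.30) were the 2 higher. Endothelial and adhesion genes had 5 of 14 higher and 1 lower (adjusted p = 0.328), the former including the adhesion molecule Selp (1.46 ± 0.21). Collagen and matrix genes had 5 of 25 higher and 4 lower (adjusted p = 0.732; median -0.04, mean 0.13, camera direction up), with Timp1 (2.46 ± 0.22) and Tnc (1.98 ± 0.22) higher. The number lower was 2 without vehicle replicate 2, MC903 replicate 2 or MC903 replicate 3, and 7 without MC903 replicate 4. Melanocyte markers had 1 of 8 higher, Dct at 0.68 ± 0.20 (adjusted p = 0.0182; list adjusted p = 0.640). The number higher was 2 without vehicle replicate 3 and 3 without MC903 replicate 4, and Dct was not called without vehicle replicate 1 (adjusted p = 0.0536) or 2 (0.0540) or MC903 replicate 3 (0.0515), nor with library sizes alone (0.0616, the highest over all alternatives; the lowest was 0.00123). None of 6 red blood cell genes passed (adjusted p = 0.321).

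Circadian clock genes, listed as a check on sampling time, were lower in 12 of 15 cases (median -1.36, adjusted p = 3.75e-10, or 0.0403 with an estimated correlation). Tef went from 145 ± 12.9 to 49.0 ± 3.36 CPM (-1.57 ± 0.12), and Per2 (-1.65 ± 0.20), Nr1d1 (-1.50 ± 0.14) and Hlf (-1.90 ± 0.17) were also lower. Arntl (-0.24 ± 0.16, adjusted p = 0.231), Clock and Cry1 (0.17 ± 0.19, adjusted p = 0.483) did not pass. The labels give no time of day for the sampling. Immediate early and heat shock genes were split, 3 of 14 higher and 2 lower (adjusted p = 0.593; median -0.08, camera direction up), with Junb at 2.30 ± 0.22. None of the 4 measured sex-linked genes passed (adjusted p = 0.742), Kdm5d being 21.7 ± 1.07 CPM in vehicle and 19.5 ± 4.41 CPM in MC903 skin.

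Of the 37 lists, 26 were called with the preset correlation, and fry called 27. With an estimated correlation, 17 of the 36 with at least 2 measured members were called. Adjusted p in those 17 ran from 0.00786 for the basophil list to 0.0442 for the interferon and itch mediator lists. The far smaller values given above rest on the preset correlation. The counts adjusted over the list alone equalled those over all genes in 25 of the 37. In 27 lists all 4 MC903 libraries lay beyond all 4 vehicle libraries in mean log2 CPM (exact permutation p = 0.0286, the smallest possible, 0.0392 after adjustment over the lists). The called lists without such separation were the adipocyte and sebaceous lists (exact permutation p = 0.0571 each) and the skeletal muscle list (0.114). The lists separated but not called with the preset correlation were all higher in mean log2 CPM. They were the sensory neuron (0.668), endothelial (0.355), barrier lipid (0.339) and B cell (1.04) lists.

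Vehicle replicate 2 stood apart. Bpifa2, a salivary secretory protein, took 4125216 counts there, 24.5% of the library, and its normalization factor was 0.775 against 1.11 to 1.13 in the other vehicle libraries. Without this library 5864 genes were called, 3044 higher and 2820 lower, and 5592 of the calls from all 8 libraries were kept in the same direction. Klk1, a gene with salivary expression, was the 1 gene called in the opposite direction, lower with all libraries and higher without this one.

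**Figure D3:**
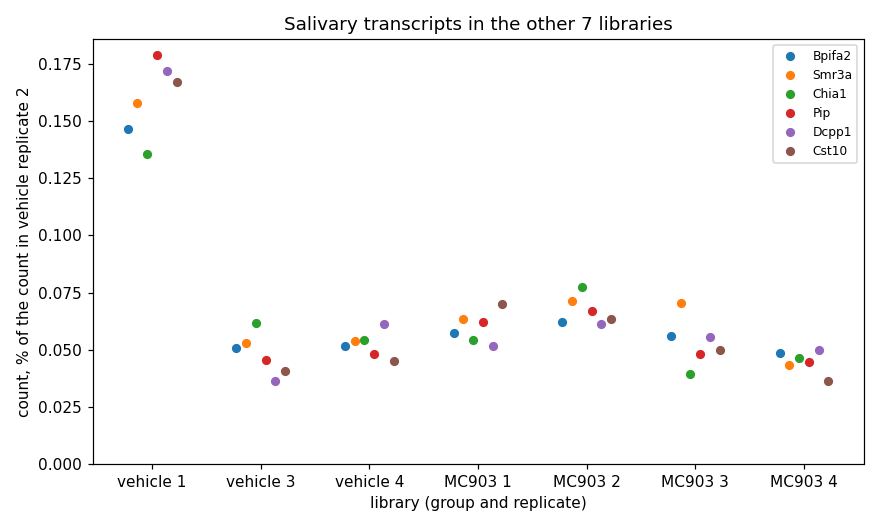
Counts of 6 salivary transcripts in each of the other 7 libraries (horizontal axis), as a percentage of the count of the same gene in vehicle replicate 2 (vertical axis). Pooled over all 8 transcripts of the set, the value is 0.0480% to 0.0628% in 6 of these libraries and 0.148% in vehicle replicate 1.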

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

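The tests of gland genes, of reads crossing between libraries, of the fall of ear-tissue markers, and of divisions of the samples for the 2-fold and list counts were chosen only after the result was seen, the division test with an estimated correlation after that with the preset one. Within each group of 4 libraries, 222 sets of values were examined for a library far from the others, meaning a gap to its neighbour, as a share of the group's range, above Dixon's 95% critical value. Of these, 21 passed, where chance alone gives about 1 in 20, or 11.1.

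Vehicle replicate 2 passed for the share of counts in its top gene (gap 0.979 of the range; 24.5% against at most 1.87%), the share in its top 10 genes (0.908; 32.9% against at most 9.59%) and its normalization factor (0.950). It also held the highest red blood cell list mean (0.903; log2 CPM 5.29 against at most 3.88) and the highest Klk6 among vehicle libraries (0.8999). Vehicle replicate 4 was lowest for the skeletal muscle list (0.957; log2 CPM 7.14 against at least 8.65) and highest for Krtap4-7 (0.867) and Tef (0.835). It alone among vehicle libraries had counts of H1foo and Sprr2k (1 for each gap). Vehicle replicate 1 was lowest for Hdc (0.835) and vehicle replicate 3 for Mcpt8 (0.932). MC903 replicate 4 was highest for Il31ra (0.905) and Rptn (0.925) and lowest for Sprr2k (0.951), Krtap6-1 (0.933) and Gjb6 (0.893). MC903 replicate 1 was highest for H1foo (0.850) and lowest for Tchh (0.899), MC903 replicate 2 was lowest for Vdr (0.853), and MC903 replicate 3 was lowest for the cell cycle list (0.865).

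The number of called genes was weighed against chance, sex and depth. Only 1 of the 35 divisions of the 8 libraries into 4 and 4, the real one, reached 6682 called genes or 2747 of at least 2-fold. The highest others gave 61 and 60. Every other division mixes treated and vehicle libraries within its groups, which widens their spread and lowers the counts. With 35 divisions, 1 of 35 is also the smallest share possible, so the division test alone does not exclude chance. The number of libraries with over 100 counts of Y-linked genes differed by 0 between the groups, and 6411 genes were called with every library thinned to the shallowest total, which argues against unequal sex and unequal depth. For the lists, 4 of the 35 divisions gave as many calls as the real 26 with the preset correlation, the highest other being 26. Those others were among the 16 divisions that kept 3 libraries of each group together (15 to 26 lists) and so kept part of the treatment contrast. The 18 that split both groups evenly gave 2 to 9. Chance is not excluded for the number of lists, and these divisions cannot decide it. With an estimated correlation only 1 of 35 reached 17 and the highest other gave 0, under the same limit of mixed divisions. Treatment remains the explanation the design names, as a hypothesis, and other differences between the 2 sets of mice were not tested.

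The salivary transcripts of vehicle replicate 2 may come from gland tissue taken with the ear. Of 8 gland epithelium genes listed for this test, 6 were highest in that library on CPM without TMM factors, with Aqp5 at 12.2 CPM against a mean of 1.30 in the other vehicle libraries and Spdef at 1.96 against 0.0211; Ano1 and Creb3l1 were not. With TMM factors 7 were, all but Creb3l1, yet Slc12a2 also stood at a mean of 94.6 CPM in the other vehicle libraries, against 156; genes of 1 tissue move together in a library, so the number has no chance level here and gland tissue stays open. Pooled per library, 8 secretory transcripts stood in the other 7 libraries at 0.0480% to 0.148% of their count there (single ones at 0% to 0.188%), while Amy1, Car6 and Dnase1 stood higher, up to 0.477%. Reads assigned to the wrong library are a candidate source: 0 of 6024 genes with at least 300 counts in every MC903 library had vehicle counts below the matching rate, but real low expression or traces of gland would also give that, so these cannot be told apart.

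Cartilage, Schwann cell, skeletal muscle and adipocyte genes were lower by similar amounts: mean log2 CPM of the cartilage list went from 4.89 to 3.89, and the other changes were -1.03, -1.02 and -1.16. The 4 lists moved by -1.30 relative to the endothelial, collagen and melanocyte lists (exact permutation p = 0.0286, the smallest possible). Both sides were chosen after their changes were seen, and the comparison lists hold genes that rose, such as Selp, Tnc and Timp1. The sebaceous list, also lower (-0.744 in mean log2 CPM), was on neither side. The contrast therefore cannot decide whether added cells diluted all resident cells equally. Vehicle replicate 2 alone is argued against as the source of the lower medians, the highest of the 4 being -0.88 without it. Fewer muscle and adipocyte genes were called without that library, as given above, so the calls in these lists did depend on it. A smaller share of deep ear tissue in the MC903 RNA stays open: the 4 changes differed by only 0.157, but lower expression in each tissue could give the same, and without tissue weights or histology these cannot be told apart. The skeletal muscle and adipocyte changes alone did not pass an exact permutation test (p = 0.114 and 0.0571).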

How the results depend on the processing

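Reads that may have crossed between libraries were subtracted only as an alternative chosen after seeing the data; all other alternatives were set before. The number of called genes, 6682, ran from 5389 with library sizes alone to 7072 without MC903 replicate 1, and the count of at least 2-fold changes, 2747, moved by more than 1.5 times only in the glmTreat test (1051, since the fold minimum is then tested). The labels do not say whether the replicate numbers pair mice. Deviations of same-numbered libraries correlated at 0.0568, -0.139, -0.118 and -0.204, and no library correlated best with its own number. These values gave no sign of pairing but cannot exclude it. With the number as a block 5705 genes were called and no list or named gene changed its call. With an estimated correlation the calls were lost of the kallikrein (median 0.94), T cell (1.53), gamma-delta T cell and innate lymphoid (0.57), mast cell (0.70), dendritic cell (0.72), sebaceous (-0.78), skeletal muscle (-0.98) and adipocyte (-1.20) lists; fry also lost skeletal muscle (-0.98) and gained barrier lipid (0.28) and B cell (1.46) genes, these medians being unmoved because only the test changes. Without the low-count filter the barrier lipid (0.26), B cell (1.45) and hair follicle (-2.08) lists were called and the type 17 median, not called either way, turned to 0.75, more genes being tested. The B cell list was called with library sizes alone (1.37) and the barrier lipid list with DESeq2 (0.29). The gamma-delta T cell list lost its call with DESeq2 (0.60), limma-voom (0.48) and crosstalk subtracted (0.57), and its median turned to -0.44 with the stricter filter, which tests fewer genes. Limma-voom also lost the type 2 cytokine (2.76) and itch mediator (0.84) lists. Where not stated otherwise, the cause was not tested. Leaving out each library in turn gave medians of -0.26 to 0.11 for type 17, -2.11 to -1.30 for hair follicle, -0.19 to 0.33 for immediate early, 0.23 to 0.31 for barrier lipid, -0.26 to 0.10 for sex-linked, -0.13 to 0.000495 for collagen and 1.09 to 1.72 for B cell genes, with calls or signs changing among them; Kdm5d, not called, ran from -0.23 to 0.00213. Depth limits the type 2 cytokines other than Il4, all of which were below the filter with all 8 libraries.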

Other observations

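The families and genes described here were chosen after their values were seen, so their tests describe these libraries and are not independent evidence. The stefin A cysteine protease inhibitors were higher in 5 of 5 measured genes (median log2 fold change 6.08; Fisher's exact test against all genes tested, adjusted over 16 tests, p = 0.00231), such as Stfa3 from 5.47 ± 1.31 to 603 ± 154 CPM (SD, n = 4). Small proline-rich proteins were higher in 13 of 14 (median 6.10, adjusted p = 1.60e-07 by the same exact test) and gasdermin C genes in 3 of 3 (median 6.05, adjusted p = 0.0307), with Gsdmc at 5.62 ± 0.26 (SE). The gasdermin C test did not pass without the low-count filter (3 of 6, median 4.05, adjusted p = 0.0637), with the stricter filter (2 of 2, adjusted p = 0.126) or after thinning (2 of 2, adjusted p = 0.109). Keratin-associated proteins were lower in 20 of 23 (median -3.11, adjusted p = 1.89e-10) and the mast cell-related Mrgprb receptors in 4 of 5 (median -3.15, adjusted p = 0.0281). Without vehicle replicate 4 the keratin-associated proteins were lower in 16 of 24 and higher in 1 (median -1.86, adjusted p = 1.86e-06), and limma-voom gave 14 of 23 lower (median -2.59, adjusted p = 0.000158), the fewest among all alternatives. Without the low-count filter 4 of 9 Mrgprb receptors were lower and 2 higher (median -1.51, adjusted p = 0.0455). Skint genes (5 of 11 lower, adjusted p = 0.1204), collagen IV chains (4 of 7 lower, 1 higher, adjusted p = 0.0925) and interleukins 19, 20 and 24 (2 of 3 higher, adjusted p = 0.233) did not pass with the settings used throughout. Skint genes passed without the low-count filter (adjusted p = 0.0215), with the replicate number as a block (6 of 11 lower, 0.0161) and without MC903 replicate 2 (6 of 11, 0.0116) or 3 (0.0491). Collagen IV chains passed without the filter (0.0215), with the block (0.0428) and without vehicle replicate 1 (0.0495) or 3 (0.0478) or MC903 replicate 2 (0.0343). These family medians kept their sign under every alternative run. Close relatives within the stefin, Sprr, gasdermin C and Krtap families can share reads, so single members are uncertain.

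Single genes outside the lists also moved far. Il19 rose from 0.758 ± 0.369 to 44.3 ± 6.86 CPM and Il24 from 0.235 ± 0.210 to 19.01 ± 5.77 CPM (SD, n = 4), and the prostaglandin synthase Ptgs2 rose by 5.42 ± 0.28 on the log2 scale (SE). Rbp2, a retinol-binding protein, went from 15.2 ± 3.45 to 580 ± 159 CPM, and Uox, urate oxidase, from 0.925 ± 0.409 to 59.1 ± 14.6 CPM. Among keratins, Krt36 (6.88 ± 0.43) and Krt84 (5.56 ± 0.40) rose, Krt14 rose by 1.87 ± 0.19, and Krt15, known from basal and hair follicle stem cells, fell from 3061 ± 912 to 564 ± 217 CPM (-2.44 ± 0.31). Krt24 (-2.99 ± 0.28), Btc (-2.40 ± 0.18), Slurp2 (-2.69 ± 0.23) and Col4a6 (-2.69 ± 0.21) were also lower.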
